A study of Drosophila melanogaster with 2 samples.

How the data were processed

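Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after egg laying, from a transgenic line that carries the product of CG4282 with GFP at its carboxy terminus. Per the labels, an antibody against GFP was used, chromatin was sheared by sonication and fragments of 200 to 800 bp were kept. There were 2 libraries in 1 group, which the labels number as biological replicates 3 and 4. The numbers are kept here. No control library, untagged line or second condition was among the samples, so no group could be compared with another and no input-based background was measured here.

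The deposited files were lists of peaks. Per the deposited file listing, each replicate had a relaxed list of peaks and background made from its alignments and 1 control file, a relaxed list was made in the same way from both replicates pooled, and an optimal list was derived from these by the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. Each list was deposited in the dm6 and the dm3 build. All coordinates below are dm6 and 1-based. The deposited signal of each peak is the authors' own enrichment value, whose scale depends on depth and on the caller. It was used to rank or describe peaks within a list. The ratio of the replicates' signals was also taken per peak or gene. That ratio was only compared between sets of peaks or genes, or set against GC content. The deposited −log10 q value had the same highest value in 1163 of the 30000 pooled peaks and was not used for ranking. Read counts and library sizes were not used here, so the depth behind each peak is unknown. Intervals on shares cover counting error over peaks or genes only.

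Checks on the files showed that the 1985 optimal peaks were exactly the 1985 pooled relaxed peaks with the highest signal. Replicates 3 and 4 shared no identical interval and no identical signal value. Of the pooled intervals, 8804 were identical to one of replicate 4 and 2 to one of replicate 3. The optimal peaks were 400 bp wide except for 111 narrower ones. The usual width was 390 bp in replicate 3 and 400 bp in replicate 4 and the pooled list. Peaks of replicate 3 with the usual width therefore could not be identical to most others. The counts of identical intervals thus cannot show how much each replicate gave to the pooled list, or that the replicates are independent.

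Summits were annotated with the Ensembl release 115 gene models on the BDGP6.54 assembly, whose arms match dm6. The annotation held 18358 genes once transposable elements were set apart. A summit within 500 bp of a transcription start site (TSS) was called promoter. The remaining summits were assigned in the order 5' UTR, 3' UTR, coding exon, non-coding exon, intron and intergenic. Optimal peaks were compared with the 27610 pooled relaxed peaks that overlapped none of them, since these could have passed. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg (BH) adjustment within each family and a threshold of 0.05. Odds ratios have Woolf 95% intervals, with 0.5 added to each cell where one was 0, and shares have Wilson 95% intervals. Differences in medians were tested by two-sided permutation tests with 100000 resamples.

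A gene counted as bound when an optimal summit lay within 500 bp of one of its TSSs. It was eligible when a pooled relaxed summit did. A summit could count for every gene with a TSS that near, yet the tests treat genes as independent. The p values of lists whose genes lie close together may therefore be too small. The design fixed 30 gene lists and 20 sequence motifs before the data were examined. Motifs were searched on both strands in the 101 bp around each summit and in windows of equal size centred 500 bp to either side. The window for the two-sided exact McNemar test was drawn at random from the upstream and the downstream one. Words of 8 bases were ranked by the same test on arms 2L, 2R and X, and the 20 with the lowest p were tested again on 3L, 3R and 4.

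The overlap between replicates was measured between the strongest peaks of each relaxed list, with as many peaks as the optimal list holds and an overlap of at least 1 bp. Chance was estimated from 1000 circular shifts of the peaks of replicate 4 along each arm, in a one-sided permutation test. The rank correlation of signal has a bootstrap interval from 1000 draws of peaks. Peaks are not independent replicates. Peaks in the 50 kb around CG4282 were set against windows taken every 5 kb along arm 2R that held at least 1 pooled relaxed peak.

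Genes are named by a rule set before the data were examined. They are CG4282, the genes with a TSS within 500 bp of the 20 strongest optimal summits, and up to 3 bound members of each list with the highest signal. Strong peaks with no such TSS are given with the gene whose intron holds them, which was added afterwards. All motifs past the threshold are named, with up to 5 words that passed on the second set of arms. The word ACACACAC, which passed as rarer at summits, was added afterwards.

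Alternatives were fixed before the data were examined. They were a stricter list made of the stronger 992 peaks, the dm3 lists, other overlap criteria, other numbers of peaks, TSS windows of 250 and 1000 bp, random positions as background, other sequence windows and word lengths, and each replicate's own strongest peaks in place of the optimal list. Another chance level for the overlap, random relaxed peaks of replicate 4 in 1000 draws, was chosen after seeing the data. The statistics were tested on simulated data. With 57% of the members of 5 lists bound in each of 20 simulations over 8405 genes, 100 of 100 planted lists were called, with 2 false calls among 480 other tests. Each planted list had at least 20 eligible genes. Smaller lists and smaller shares were not simulated, so the power to call them is unknown. A simulated promoter share of 56.6% over 1985 peaks was returned as 57.2%, a simulated overlap between replicates of 50% as 50.5%, and a log2 difference of 0.30 in signal as 0.30. The planted word ranked at the top, and no motif was called at random positions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.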

Results

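Binding of the GFP-tagged product of CG4282 was mapped by ChIP-seq in 2 biological replicates, numbered 3 and 4, of whole Drosophila embryos aged 0 to 24 h. CG4282 (FBgn0034114, 2R, 16322186 to 16324801, plus strand) was placed here among genes for zinc finger proteins with a ZAD domain. The deposited optimal list held 1985 peaks, with a median signal of 93.8 and values from 66.9 to 1066. All lay on arms 2L, 2R, 3L, 3R, 4 and X. With 1 group and no control library among the samples, the comparisons were between the replicates, between optimal and weaker peaks, and between gene groups and sequences. Signal shared by other anti-GFP immunoprecipitations was not measured here.

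The strongest optimal peaks lay mostly at promoters and in introns. The highest signal, 1066, was at 3L 19590456 to 19590777, with its summit 89 bp from the TSS of CG14100. It ranked 1 in each replicate. The next lay in an intron of ush (2L, 480915 to 481267, signal 965), which encodes a cofactor of GATA transcription factors, and at the promoter of Ugalt (X, 2703719 to 2704048, signal 822), a UDP-galactose transporter. All 20 of the strongest optimal peaks were among the strongest 1985 of each replicate, and none ranked below 28 in either. They were chosen by the signal of both replicates pooled, so strength in each is partly built into the choice.

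Of these 20 peaks, 13 had a summit within 500 bp of a TSS. They included the promoters of px (721), a wing vein gene, of PNPase (672), a mitochondrial RNA-processing enzyme, of CG1888 (603), and of Rtnl1 (552), a reticulon of the endoplasmic reticulum. A peak of signal 505 lay 477 bp from a TSS of ph-p, a Polycomb group gene. Other summits lay near the starts of 2 genes each. The peak at 3L 22878744 to 22879059 (signal 696) was 80 bp from Chro, which encodes the chromatin protein Chromator, and 185 bp from Ssl1, a subunit of the transcription factor TFIIH. Further pairs were Shc and Atat (560), DPCoAC and CG5180 (552), CenG1A and mRpS23 (504), and CG32176 and Coq4 (500). The summit of signal 523 lay 135 bp from mRpL41 and 443 bp from the non-coding gene lncRNA:CR44463. The remaining 7 included introns of CG11050 (808), Lk6 (754), CG32772 (575), CG9663 (552) and NFAT (486), and an intergenic site at 2R 13035207 to 13035440 (487), whose summit was 11916 bp from the nearest TSS.

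Among the strongest 1985 peaks of each relaxed list, 1315 of those of replicate 3 overlapped one of replicate 4, or 66.2% (Wilson 95% interval, 64.1 to 68.3). Circular shifts gave a mean overlap of 1.12% (SD 0.247) and a highest of 1.91%, and the one-sided permutation p was 0.001, the smallest that 1000 shifts can give. The overlap was 84.0% among the strongest 50 peaks and 57.3% among the strongest 5000. Genes with moderate peaks did not always rank alike. Of the 62 named members of gene lists, 54 were among the strongest 1985 of replicate 3 and 58 among those of replicate 4. The peaks at wg, which encodes a Wnt ligand, at brk, a repressor in BMP signalling, at E(spl)mbeta-HLH, a Notch target, and at CycA, a mitotic cyclin, ranked 649, 1007, 586 and 1116 in replicate 4. In replicate 3 they ranked 7898, 6788, 7333 and 6242. In the other direction, tud and orb, both germline genes, ranked 570 and 1301 in replicate 3 and 3940 and 4790 in replicate 4. The others outside the strongest 1985 were pad, Mcm2, Tm1 and Obp99b in replicate 3 (ranks 2086 to 2436), and SerRS and Atg2 in replicate 4 (2592 and 2529). No gene list differed past the threshold between peaks of 1 replicate only. Over the 1983 optimal peaks that met a relaxed peak in both replicates, Spearman's rho of the 2 signals across peaks was 0.568 (bootstrap 95% interval, 0.531 to 0.603). Optimal peaks are the strongest of the pooled list, so a moderate one that is weak in 1 replicate tends to be strong in the other. That choice can lower rho and bring in genes that rank apart, such as wg and brk.

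**Figure D1:**
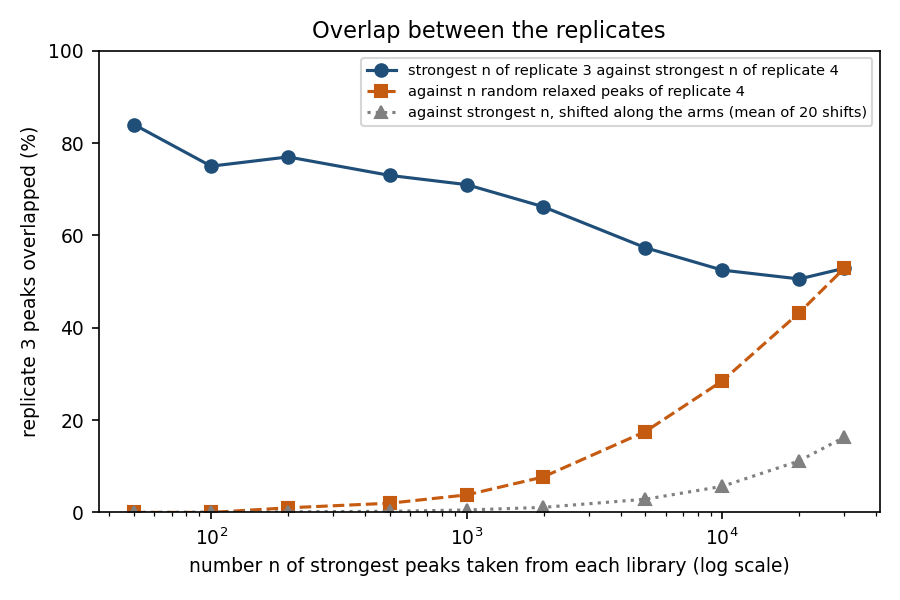
Percent of the strongest n peaks of replicate 3 that overlap the strongest n of replicate 4 (circles), n random relaxed peaks of replicate 4 (squares), or its strongest n after shifting along the arms (triangles), against n on a log axis. The overlap falls from 84.0% at 50 peaks to 66.2% at 1985, where the random relaxed peaks drawn for the figure give 7.66%. Over 1000 draws of random relaxed peaks the mean was 7.99% (SD 0.604).

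No optimal peak lay at the promoter of CG4282 itself. A tagged transgene can add copies of its own locus, so peaks around the gene were counted first. The nearest pooled relaxed peak had its summit 11 bp upstream of the TSS, with a signal of 36.6 and rank 7695. In replicate 3 a summit 1 bp upstream ranked 2063, and in replicate 4 one 248 bp downstream ranked 9086. The 50 kb around the gene held 2 optimal peaks, at 14492 and 16195 bp from the TSS, with signals of 67.5 and 70.2. It held 22 pooled relaxed peaks, against a median of 14 in windows of arm 2R, which placed it at percentile 78.9. Replicate 4 had 27 relaxed peaks there (percentile 91.2) and replicate 3 had 14 (percentile 53.1).

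Promoters held 1294 of the 1985 optimal summits, or 65.2% (63.1 to 67.3), against 27.1% of the 27610 relaxed peaks that overlapped none of them. The odds ratio was 5.04 (4.58 to 5.55, Fisher's exact test, adjusted p = 6.35e-252). Promoters within 500 bp of a TSS make up 13.6% of the arms. Introns held 486 summits, 24.5% against 29.0% (adjusted p = 1.75e-05, Fisher's exact test), and intergenic sequence 164, 8.26% against 12.8% (adjusted p = 1.20e-09, Fisher's exact test). The classes share a single total, so the higher promoter share by itself lowers the others. Of the 691 optimal summits outside promoters, 486 were in introns and 164 intergenic. The 27610 relaxed summits had 7482 at promoters, 8015 in introns and 3530 in intergenic sequence. Outside promoters, introns and intergenic sequence thus held a larger part of the optimal than of the relaxed summits, which was not tested. Coding exons held 8 optimal summits, 0.403% against 25.7%, with an odds ratio of 0.0117 (0.00584 to 0.0234), which was 0.0452 with the strongest peaks of replicate 4 alone and 0.0272 against random positions. Shares in 3' UTRs (0.605% against 3.26%) and 5' UTRs (0.504% against 1.22%) were also lower, and non-coding exons did not pass (adjusted p = 0.133, Fisher's exact test). The lower share in 5' UTRs did not pass when the strongest peaks of replicate 4 were used alone or when random positions were the background.

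**Figure D2:**
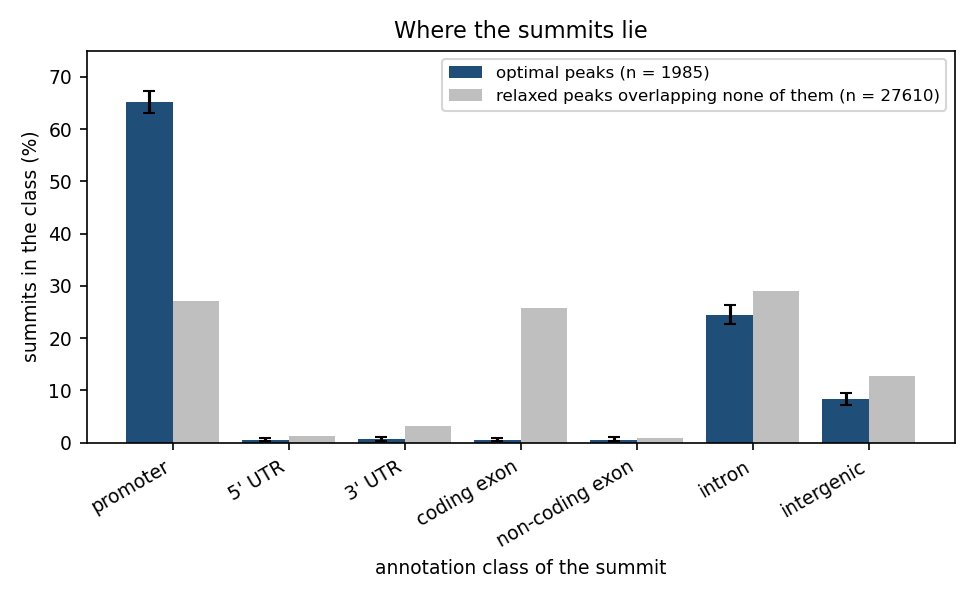
Percent of summits in each annotation class for the 1985 optimal peaks (dark bars, with Wilson 95% intervals) and the 27610 relaxed peaks that overlap none of them (grey bars). Promoters hold 65.2% of the optimal and 27.1% of the relaxed summits, and coding exons 0.403% and 25.7%.

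The median distance from a summit to the nearest TSS was 185 bp (quartiles 62 and 1027) for optimal peaks and 1370 bp (442 and 3875) for the relaxed ones. The difference of medians was -1185 bp (permutation p = 1e-05, the smallest that 100000 resamples can give). Optimal promoter summits lay upstream of the nearest TSS in 962 of 1294 cases, or 74.3%, with a median position of -59 bp. For relaxed promoter summits the share was 43.1% and the median position 31 bp (Fisher's exact test, p = 2.64e-98). Starts on both strands lay within 500 bp of 481 optimal promoter summits, 37.2% (34.6 to 39.8) against 17.8% (Fisher's exact test, p = 5.96e-51). Chro and Ssl1, and RpS27 and Nup37, are pairs of this kind. The last 2 counts were added after the distances had been seen. They are linked, since a summit between starts that point away from each other is upstream of either. Promoters with starts on a single strand were not counted apart, so the upstream share may partly reflect the paired starts.

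**Figure D3:**
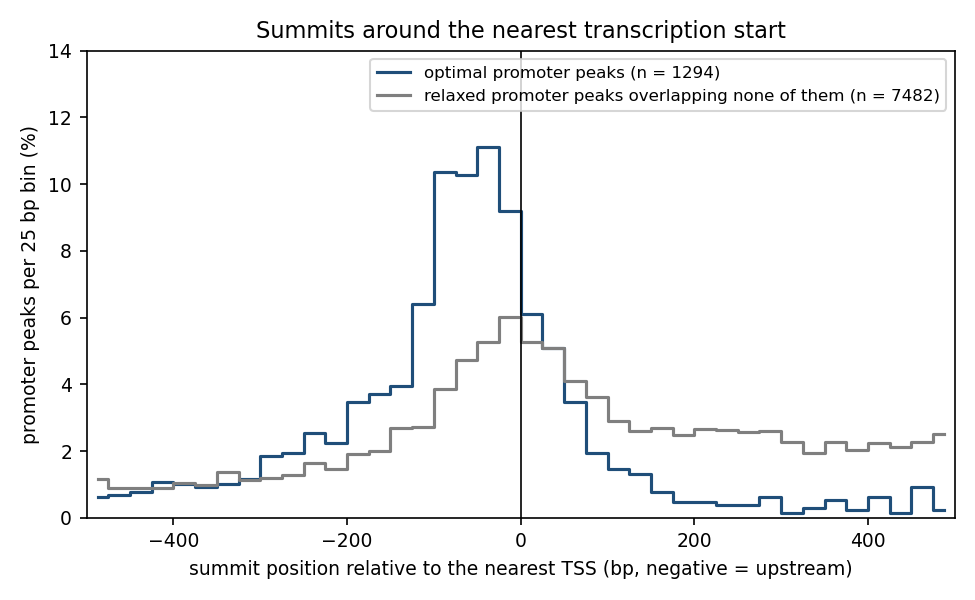
Position of promoter summits relative to the nearest TSS, in percent of promoter peaks per 25 bp bin, for 1294 optimal peaks (dark line) and 7482 relaxed peaks that overlap no optimal one (grey line). Negative positions are upstream. The optimal summits centre at -59 bp and the relaxed ones at 31 bp.

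No chromosome arm passed the threshold, and 1 had an unadjusted p under 0.05 in Fisher's exact test. Arm 2R held 18.5% of optimal and 20.4% of relaxed peaks, and X held 17.1% and 15.5% (Fisher's exact test, adjusted p = 0.151 for each). Density ranged from 13.9 peaks per Mb on 3L to 16.4 on 2L among the large arms. The small arm 4 held 9 peaks, or 6.68 per Mb. With the strongest peaks of replicate 3 alone, X held 18.3% against 15.8% (Fisher's exact test, adjusted p = 0.0170).

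Genes for cytosolic ribosomal proteins were bound far more often than others. Of 81 eligible members, 46 had an optimal summit within 500 bp of a TSS, 56.8% against 20.4% of other genes, with an odds ratio of 5.14 (3.30 to 8.01, Fisher's exact test, adjusted p = 2.76e-11 over 29 lists). RpS27, RpL7 and RpL23A, which encode subunits of both ribosomal particles, had the highest signals, 331, 303 and 245, with summits 11, 34 and 108 bp from a TSS. All 3 ranked within the strongest 167 of each replicate. In all, 1740 of 8405 eligible genes were bound, or 20.7%, of which 1595 were protein-coding. Cuticle protein genes (0 of 27, adjusted p = 0.0463, Fisher's exact test) and chemoreceptor genes (0 of 25, adjusted p = 0.0491, Fisher's exact test) were bound less often. Both calls ended with the stricter list, the TSS window of 250 bp and the strongest peaks of replicate 3 alone, and that of the cuticle proteins also with those of replicate 4 alone. The number bound was 0 in each of these settings.

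No other list passed. Among lists for growth and housekeeping, 17 of 53 mitochondrial ribosomal protein genes were bound (adjusted p = 0.245, Fisher's exact test), with mRpL41 (523), mRpS23 (504) and mRpS10 (390) highest. Vacuolar ATPase genes, whose products acidify organelles, counted 8 of 21 (adjusted p = 0.245, Fisher's exact test), led by Vha16-5 (216) and Vha55 (192). Translation factors counted 12 of 39, with eIF6, which acts on the large ribosomal subunit, at 458 and eIF3c at 158. Oxidative phosphorylation counted 11 of 51, with ND-MWFE at 167 and COX5A at 150, and the proteasome 7 of 29, with Rpn5 at 197. Aminoacyl-tRNA synthetases counted 5 of 23 (GluProRS, 108), nucleoporins 5 of 16 (Nup37, 331), autophagy 5 of 14 (Atg17, 105), DNA replication 5 of 17 (PCNA2, 100.6), heat shock proteins 2 of 9 (Hsp83, 158) and the chaperonin CCT 0 of 4. Among genes for small RNAs, tRNA genes counted 10 of 96, 10.4% against 20.8% (adjusted p = 0.0784, Fisher's exact test), and snRNA genes 6 of 17 (snRNA:U1:95Ca, 104). The tRNA genes passed as bound less often with the strongest peaks of replicate 4 alone and with TSS windows of 250 and 1000 bp. No replication-dependent histone gene was eligible. When all genes of the biotype were, mitochondrial ribosomal proteins passed as bound more often.

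Among regulators of chromatin and development, Polycomb and trithorax group genes counted 7 of 16, with an odds ratio of 2.99 (1.11 to 8.03, Fisher's exact test, adjusted p = 0.184), and passed with a TSS window of 1000 bp and with all genes of the biotype eligible. Their highest signals were at ph-p (505), at Trl (177), which encodes GAGA factor, and at Su(z)12 (138), a subunit of the PRC2 complex. Insulator and boundary protein genes counted 4 of 12, led by Chro (696), Trl and Dref (149), the last encoding the factor that binds the DNA replication-related element (DRE). ZAD zinc finger genes counted 3 of 13, with Sry-delta at 163, pad at 87.0 and hang at 84.8. Segmentation and Hox genes counted 2 of 20, bcd (89.1) and wg (82.9), and Notch, Wnt and BMP signalling 4 of 13, with N (94.1), E(spl)mbeta-HLH (86.0) and brk (75.4). Cell cycle regulators counted 3 of 19 (polo, 117), muscle genes 4 of 10 (Msp300, 218, and sls, 177), neural genes 1 of 12 (elav, 148) and germline genes 2 of 6 (tud, 89.2). Odorant-binding proteins counted 1 of 11, seminal fluid proteins 1 of 3, eggshell proteins 0 of 6 and antimicrobial peptides 0 of 2.

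**Figure D4:**
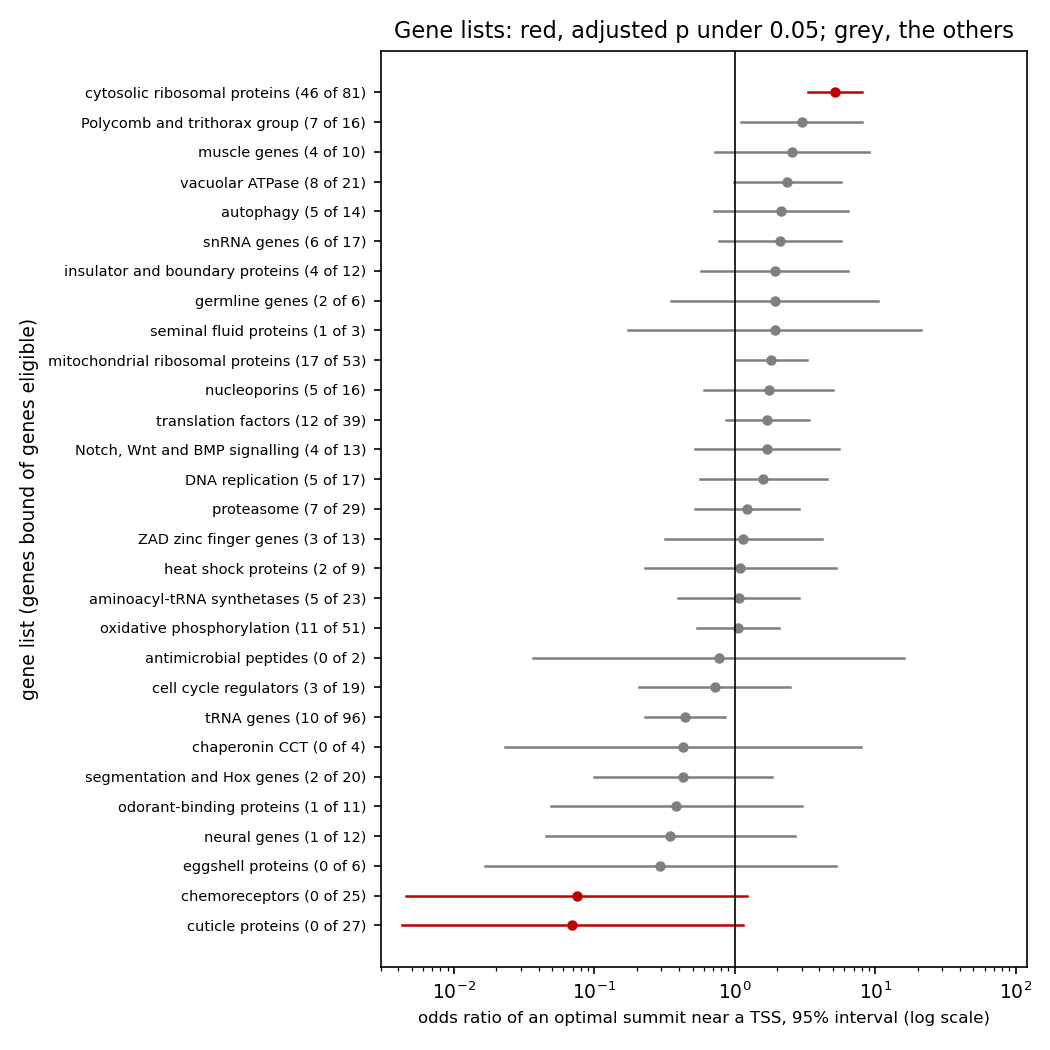
Odds ratio of an optimal summit within 500 bp of a TSS for each of 29 gene lists against the other eligible genes, with 95% intervals, on a log axis. Lists past the adjusted threshold are red. Cytosolic ribosomal proteins stand at 5.14, and cuticle proteins and chemoreceptors have 0 bound members.

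Of the 20 motifs tested, 6 were more frequent at summits than beside them and 1 was less frequent. The BEAF-32 core, recognised by an insulator protein and contained in most forms of the DRE, occurred in the windows around 417 of 1985 summits and in 209 of the windows beside them (exact McNemar test, adjusted p = 1.63e-18 over 20 motifs). The DRE occurred at 6.35% against 1.51% (exact McNemar test, adjusted p = 2.20e-15) and Motif 7, a core promoter element, at 4.84% against 0.705% (exact McNemar test, adjusted p = 2.20e-15). Against relaxed peaks of the same annotation class the excess was smaller, with 15.2% of those for the BEAF-32 core, 2.92% for the DRE and 2.26% for Motif 7, and the 3 calls held. Motif 1, the site of M1BP, was at 0.856% against 0.101%, Motif 6 at 0.655% against 0 of 1985 windows, and the Su(Hw) core at 0.403% against 0 of 1985. Averaged over the windows on both sides, Motif 6 was at 0.0756% and the Su(Hw) core at 0.101%. The CA repeat was rarer at summits, 2.22% against 4.63% (exact McNemar test, adjusted p = 0.000206). Among motifs that did not pass were GAGA factor (12.7% against 13.9%), Zelda (0.554% against 0.856%), the TATA box (1.71% against 1.41%), the initiator (8.66% against 8.72%) and Pho (14.4% against 14.5%). The Su(Hw) call was lost under each of the 6 alternatives, that of Motif 1 in windows of 51 bp and against relaxed peaks of the same annotation class, that of Motif 6 in the stricter list, and that of the CA repeat with the strongest peaks of replicate 4 alone. Other motifs gained a call. GAGA factor passed as lower at summits in the stricter list, with the strongest peaks of replicate 3 alone, and against relaxed peaks of the same class, and its longer form in the former 2 of these. GATA passed as higher with the strongest peaks of replicate 3 alone and against the same class, and Motif 5 with those of replicate 3 alone and in wider windows. Against the same class the TATA box passed as higher and Pho as lower. In wider windows Zelda passed as lower and the E-box CAGCTG as higher, and the homeodomain core passed as higher in the stricter list.

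**Figure D5:**
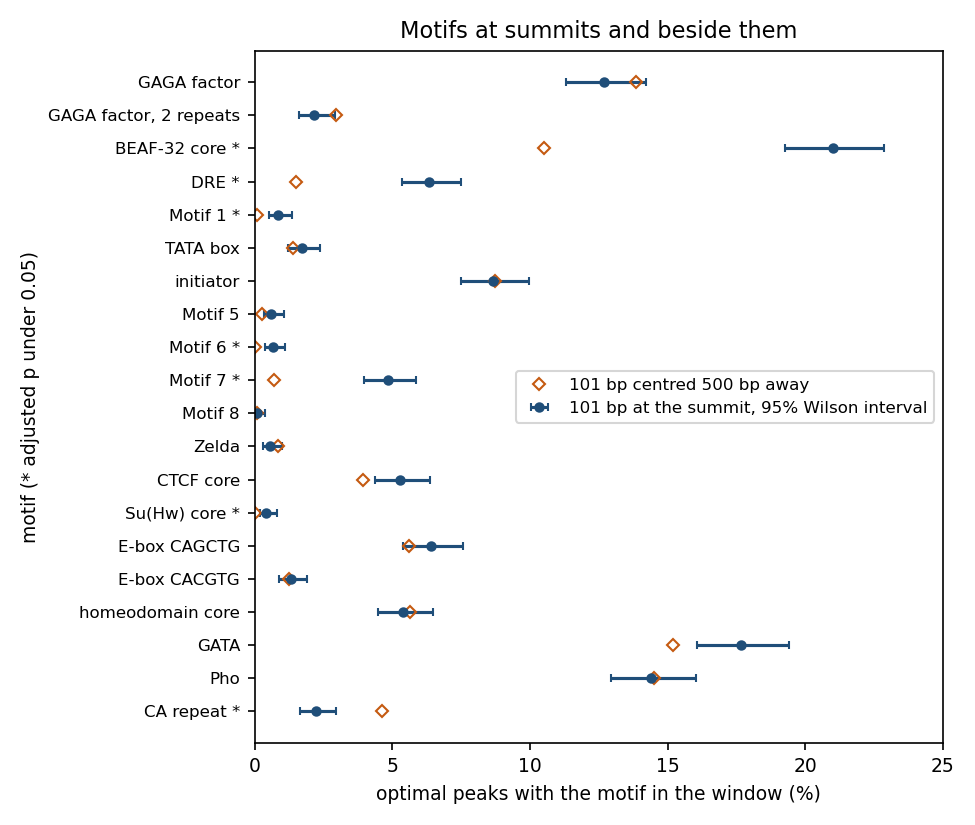
Percent of the 1985 optimal peaks with each motif in the window at the summit (circles, with Wilson 95% intervals) and in a window centred 500 bp away (diamonds). Asterisks mark adjusted p under 0.05. The BEAF-32 core is at 417 summits against 209 flanking windows, and the DRE at 6.35% against 1.51%.

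Of the 20 words of 8 bases with the lowest p on 2L, 2R and X, 13 passed again on 3L, 3R and 4. Many of these overlap as forms of the same sequence, so they stand for fewer separate sequences. ACACACAC passed as rarer at summits, 1.91% against 3.81% on the second set of arms. ATCGATAG, an extended DRE, was at 4.39% of 1093 summits on the first set of arms and 0.0915% of flanking windows, and at 4.37% and 0.897% of 892 on the second (exact McNemar test, adjusted p = 1.85e-05). TATCGATA, also a form of the DRE, was at 4.37% against 0.673% on the second set. CACAGTGG was at 4.48% against 0.224% (exact McNemar test, adjusted p = 1.49e-09), and CACTGTGC, which overlaps its reverse complement, at 4.60% against 0.224% (exact McNemar test, adjusted p = 2.15e-09). CAACACTG was at 3.81% against 0.336% (exact McNemar test, adjusted p = 8.22e-07). At the shared start region of DPCoAC and CG5180, the 41 bp around the summit (3R, 20557744 to 20557784) read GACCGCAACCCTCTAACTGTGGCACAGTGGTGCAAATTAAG, which holds CACAGTGG. This was the only one of the 20 strongest summits with that word within 50 bp.

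Promoter peaks were about as strong as the others. Their median log2 signal was 6.57, higher by 0.06 than that of the others (permutation p = 0.0507), and the difference passed the threshold with a TSS window of 1000 bp and with the strongest peaks of replicate 4 alone. The promoter share was 68.0% among the strongest 497 peaks and 63.1% among the weakest 496. The log2 ratio of the signal of replicate 4 to that of replicate 3 differed by -0.02 between promoter and other peaks (permutation p = 0.398).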

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

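The alternatives were fixed before the data were examined, except random relaxed peaks as the chance level for the overlap, which were chosen after seeing it. The overlap between replicates, the promoter share and the shorter TSS distance kept their direction and stayed past the threshold under every alternative run for them. The overlap ranged from 60.3% to 71.1%, and the correlation of signals from 0.546 to 0.568. The promoter share ranged from 55.3% with a TSS window of 250 bp to 74.5% with 1000 bp. The stricter list holds 992 peaks by construction. Annotation classes past the threshold numbered 5 to 6, and motifs 5 to 10, with 5 without replicate 3 and 10 without replicate 4. The window around CG4282 stood at percentile 64.4 to 85.4 with other widths, 53.1 without replicate 4 and 91.2 without replicate 3. Lists past the threshold numbered 3, and 1 in the stricter list, 5 with a TSS window of 1000 bp, 6 when all genes of the biotype were eligible (1 of them the histone genes, none of which had a relaxed peak), and 1 to 3 with a replicate left out. Cytosolic ribosomal proteins passed in each of these, with odds ratios from 3.90 to 7.97. Words that passed on the second set of arms numbered 13, and 7 when the words were ranked anew in the stricter list, which has fewer peaks. Of the 13 themselves, 11 kept their call when tested in the stricter list. Chromosome arms past the threshold numbered 0 to 1 with a replicate left out. The log2 difference in signal between promoter and other peaks, 0.0648, was 0.00987 with a TSS window of 250 bp (permutation p = 0.734), 0.0295 in the stricter list (permutation p = 0.493), 0.0886 with a TSS window of 1000 bp (permutation p = 0.0133) and 0.0654 to 0.0710 with a replicate left out, past the threshold without replicate 3 (permutation p = 0.0170). The homeodomain core, at 5.39% of summits against 5.64% beside them, was at 6.35% of summits in the stricter list and higher than beside them (exact McNemar test, adjusted p = 0.0199). The word ACACACAC, rarer at summits, ranged from 1.25% to 3.09% with a replicate left out, and its direction turned without replicate 3 (exact McNemar test, adjusted p = 0.659). Apart from the list sizes, the cause was not tested. Leaving out a replicate was not possible for the optimal list itself, the overlap, the correlation and the difference between replicates. Read depth was not used here, so what it limits was not measured.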

Other observations

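Of the tests in this part, those chosen only after the result was seen are that of CACAGTGG outside promoters, those of housekeeping genes as 1 group, that of patterning and signalling promoters, and the comparisons of words by class and signal, of narrow peaks, of the distances to CACAGTGG and the DRE, of coding exons between the replicates, and of motifs at ribosomal protein genes.

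The words found at summits differed in where they lay. ATCGATAG was at 85 of 1294 promoter summits and at 2 of the 691 others, and CAACACTG at 65 and 6. CACAGTGG was at 59 promoter summits, 4.56%, and at 31 of the 486 in introns, 6.38%. Its share at promoter summits did not differ past the threshold from that at all others. The odds ratio was 0.799 (0.527 to 1.21, Fisher's exact test, adjusted p = 0.426). The word was at 9.26% of the strongest 497 peaks and at 2.22% of the weakest 496. The odds ratio for the strongest against the rest was 2.82 (1.87 to 4.25, Fisher's exact test, adjusted p = 2.30e-05). Of the 20 strongest peaks 1 held the word, and 20 are too few to set against that share. The base before it was G in 86.1% of the copies at summits. Of 5536 copies on the arms, 257 lay in optimal peaks, or 4.64%. The 111 peaks narrower than usual had a median rank of 58 and held the word in 10.8% of cases against 4.59% (Fisher's exact test, p = 0.0101).

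CACAGTGG may be part of a sequence that the tagged protein, or a partner, recognises. Promoter composition alone is argued against by the summits outside promoters, where 5.64% held the word against 0.724% beside them (exact McNemar test, p = 5.65e-08). The word had been picked by the same test on 2L, 2R and X, whose summits are included, so this p is likely too small. A repeated element common to these peaks is argued against as well, since 2.04% of 98 windows with the word shared a 20-base stretch with another. The windows were compared only with one another and for exact matches. A repeat with copies elsewhere in the genome, or with diverged copies, was therefore not tested. Whether the word marks the crosslinked site cannot be told apart from a place nearby. The median distance from summit to word was 56.5 bp (48.5 to 67.5). The whole interval lay above the distance set beforehand for a word at the crosslinked site. Its lower end fell just under the distance set for rejecting that site. The median distance to the DRE was 59.5 bp (permutation p = 0.759 for the difference).

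Among the strongest peaks, the 668 of replicate 4 only had a mean GC content of 46.1% and the 670 of replicate 3 only a mean of 38.9%, against 39.0% for the 1315 shared, and coding exons held 29 and 2 of them (Fisher's exact test, p = 1.81e-07). A GC bias of the whole library cannot be told apart from a difference among the strong peaks, because the weaker 15000 peaks of replicate 4 were higher by 1.49 points (1.29 to 1.70), between the bounds set beforehand. Stronger binding at patterning and signalling genes such as wg and brk in the embryos of replicate 4 also stays open. The log2 ratio at 29 of their promoters was higher by 0.35 (0.04 to 0.70) after the trend with GC content around the TSS was removed. That trend was weak (Spearman's rho 0.0736), while at optimal promoter peaks the ratio followed summit GC content more closely (0.266). The adjustment therefore could not remove a GC effect of the latter kind. The 29 were also taken from the lists that hold the genes that prompted the idea. Among genes near peaks of 1 replicate only, segmentation and Hox genes counted 0 in replicate 3 and 2 in replicate 4, signalling genes 0 and 3, and no list passed (Fisher's exact test, adjusted p = 1 for each).

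Ribosomal protein genes may share a promoter feature linked to this binding, a hypothesis found and tested on the same data. The genes of the other 11 growth and housekeeping lists were bound more often than the rest as well, but less so, with an odds ratio of 1.504 (1.15 to 1.97), below the interval of the ribosomal protein genes. Respiratory chain, proteasome and translation factor genes alone had 1.30 (0.854 to 1.97), and as transcription was not measured here, its level stays open. The odds ratio of the ribosomal protein genes was 5.17 (3.30 to 8.09) within classes of promoter GC content and 4.82 (3.07 to 7.57) within classes of neighbouring genes. The DRE was at 29.8% of 47 ribosomal protein peaks and 7.94% of 1247 other promoter peaks (Fisher's exact test, adjusted p = 0.000326). The BEAF-32 core was at 25 and 308 of these peaks (Fisher's exact test, adjusted p = 0.000551). The E-box CACGTG was at 4 and 15 (Fisher's exact test, adjusted p = 0.0187). CACAGTGG was at 0 and 4.73%, a difference that did not pass (Fisher's exact test, adjusted p = 0.635). All of these are optimal peaks, and ribosomal protein genes without one were not compared. The shares therefore cannot tell a feature linked to binding from one common to ribosomal protein promoters.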
